A study of Mus musculus with 4 samples.

How the data were processed

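H3K79me2 ChIP-seq and input libraries were made from formaldehyde-fixed BMDCs given PBS or lysine and sequenced with paired ends, per the labels' protocols. Each condition has 1 H3K79me2 sample and 1 input sample. Groups were taken from the sample titles. A broad and a gapped peak list of each of the 2 H3K79me2 samples were analysed, and the inputs were not analysed here.

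The submitters' processing notes name cutadapt 1.18, Trimmomatic 0.38, FastQC, Bowtie2 2.3.4.1, Picard, MACS2 2.1.2, ChIPseeker and the build GRCm38, without roles or settings. Peaks were deposited per sample, not on pooled samples. The calling thresholds and whether the inputs served as controls are not given in the sources used here. The files have no header, so their columns were read by the layout of MACS2 broad calls. The deposited fold enrichment of a peak is a linear ratio of its signal to the local background, averaged over the peak. The deposited significance values are −log10 p and −log10 q, the lowest −log10 q being 1.37 in PBS and 1.32 in lysine. The deposited score is 10 times the −log10 q without decimals, which 0 PBS peaks and 1 lysine peak did not match. The authors' gapped lists hold the same regions as the broad lists, with the number of narrow blocks in each and their positions. Blocks of 1 bp only mark a region's end and were left out, leaving 334 PBS and 257 lysine regions without a block. All of these values depend on the depth and enrichment of the library, so in the comparisons they were used to describe, rank or filter peaks within a list and not as a measure of change between lists. The same minimum was applied to both lists in the alternatives. A check of depth in the closing section does set the lists side by side, by the median −log10 p of their peaks in fold bins of 0.25 from 3.5 to 8. No list gives read counts, so the depth per sample is unknown and no error from it could be given.

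Peak sets were compared by position. A peak was shared if at least 1 bp of it overlapped the other list, and the level without relation was taken from 100 circular shifts within chromosomes (seed 7). Genes came from a RefSeq table of GRCm38.p6, the build of the peak lists, with 21900 protein-coding genes. Genes of the autosomes, the sex chromosomes and the mitochondrial genome were eligible. The covered length of a gene is the number of its bp, from end to end, under broad peaks, and a gene with at least 500 bp is called marked. Of these genes 3848 overlap another protein-coding gene and share covered length with it. The table gives the ends of a gene without strand or exons. Location and position along genes, planned from the gene's 5' end, were therefore computed from either end or the nearer end, and exons and introns were not separated. A peak whose midpoint lay within 1 kb of a gene end was counted there first, then inside a gene, then between genes, and covered length was divided by position in the same order. Each list median and mean of lysine minus PBS covered length was placed among 10000 random lists of the same size matched in 10 bins on mean covered length, and shares of genes with a peak among lists matched on gene length. With 1 library per condition such percentiles are no test.

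The 23 gene lists, the thresholds and the rule for named genes were fixed before the data were examined. The function lists were MHC class II and class I presentation, dendritic cell identity and maturation, cytokines and chemokines, Toll-like receptor and NF-kB signalling, type I interferon response, lysine transport and catabolism, amino acid sensing and mTORC1, integrated stress and unfolded protein response, H3K79 methylation machinery and partners, methionine and S-adenosylmethionine metabolism, glycolysis, ribosomal proteins, lysosome and autophagy, and cell death and ferroptosis. The other 8 held markers of macrophages and monocytes, neutrophils, mast cells and basophils, T and NK cells, B cells, erythroid and megakaryocytic cells, stromal and endothelial cells, and neuronal and hepatic genes taken as silent. The list of silent genes also held some genes of muscle and pancreas. Of 621 entries 618 matched a protein-coding gene, 3 of them through a synonym, and 5 genes stand in 2 lists. Mx1, Mx2 and Tpsab1 did not match a protein-coding gene. Named genes are the 10 with the most covered length in 1 library and none in the other, in each direction, and the 10 marked in both with the largest difference, in each direction. Also named are the 5 widest and 5 most enriched peaks of each list, Dot1l, and from each list the 2 genes with the most covered length and the 2 with the largest difference. A gene and a peak that the rule names are not reported here.

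Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Overlaps and covered lengths were checked against bedtools 2.31.1, with 0 differences. The list percentiles were tested on simulated data of 21900 genes with 200 changed genes: 4 of 4 lists of 25 genes whose covered length was multiplied by 0.5, and 4 of 4 multiplied by 0.25, fell under the 5th percentile, and 2 of 40 unchanged lists lay outside the 5th to 95th. The changed lists held only genes covered in PBS, and all their members changed. No simulated gene gained a first peak, and there was no general loss of covered length. The real lists also hold uncovered genes, 7 of 17 for MHC class II presentation. The simulation therefore does not give the power for the real lists. Intervals of shares are 95% Clopper-Pearson intervals. In the closing section, the interval of the peak number ratio was made from the Clopper-Pearson interval of the lysine share of all peaks counted, and those of the depth ratio, of the differences in shared peaks and of the ratio of ratios are the central 95% of 100 bootstrap resamples of the peaks. All of these cover counting error only and treat peaks as independent. Alternatives tried were a −log10 q of at least 2 or 5, a fold of at least 4, equal numbers of peaks, peaks of at least 1 kb, joining of peaks within 2 kb, autosomes alone, narrow blocks, other overlap rules, other minimum covered lengths, genes that overlap no other gene, and other widths of the gene end zone.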

Results

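H3K79me2, the dimethylated form of a lysine in the core of histone H3, is made by the methyltransferase Dot1l and lies over transcribed genes. It was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in bone marrow-derived dendritic cells (BMDCs) of C57BL/6J mice. These are antigen-presenting cells obtained by culturing bone marrow. The cells were given PBS, or the essential amino acid lysine at 18 mM for 6 h. The labels state no time for PBS, so whether both cultures were kept equally long is unknown here. Each condition had 1 H3K79me2 library and 1 input library, 4 samples in all, and the broad peak lists of the 2 H3K79me2 libraries were compared. There are no replicates, so no difference between the conditions could be set against a spread between libraries and no test was made. Each value describes these 2 libraries. The peak lists give no read totals, so the depth is unknown. Fold enrichment and −log10 q of a peak are the authors' values and were used in the comparisons to describe, rank or filter the peaks of the list they come from. Intervals of shares are 95% Clopper-Pearson intervals and cover counting error only. Coordinates are on GRCm38.

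The comparison asks where H3K79me2 lay in BMDCs given lysine and in BMDCs given PBS. The called mark was less extensive in the lysine library, with 9805 peaks over 5.40 Mb against 11926 peaks over 6.78 Mb in PBS. The lysine list thus had 82.2% of the PBS peak number and 79.6% of its covered length. Typical peaks had nearly the same width, with a median of 450 bp in lysine (quartiles 358 and 586 bp) and 456 bp in PBS (362 and 603 bp). Long peaks of 1 kb or more numbered 835 in lysine and 1180 in PBS. Covered length in lysine was below that in PBS on all 19 autosomes and on the X, from 0.751 of the PBS length on chromosome 10 to 0.867 on chromosome 19, and 0.755 on the X. The gapped lists, which give the narrower blocks inside the same regions, held 9784 blocks in lysine and 11921 in PBS.

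The widest peak of both lists lay at chromosome 17, 39843280 to 39848761 in PBS (5482 bp) and 39843320 to 39848754 in lysine (5435 bp), over the ribosomal RNA pseudogene Rn18s-rs5 and the non-coding gene AY036118. Its fold was 2.15 in PBS and 2.27 in lysine, below the list medians of 4.52 and 4.48. No filter for repeats or other regions that are hard to map was applied here. The second widest PBS peak (4860 bp) lay over Malat1, a nuclear long non-coding RNA (chromosome 19, 5796384 to 5801243). No lysine peak overlapped it. Next came peaks over Ier2 (4758 bp) and Junb (4467 bp), both immediate early genes, and Il3ra (4457 bp), the alpha subunit of the interleukin-3 receptor. In lysine the next widest peaks lay over Klf6 (3751 bp), a zinc finger transcription factor, at chromosome 9, 3022306 to 3025873, outside any gene (3568 bp), over Ier2 (3408 bp), and over Kansl1 (3370 bp). Among the highest fold enrichments within the PBS list were those at Hnrnpc with Rpgrip1 (17.5), Tepsin with Ndufaf8 (16.8), Rab5b with Pmel (16.0) and Nubp2 with Spsb3 (15.5). Within the lysine list they were at Canx (18.8), Mxd1 (16.6), Prkaca (15.6), Snhg10 with Glrx5 (15.0) and Arid4a (14.3). Each of these strongest peaks was overlapped by 1 peak of the other list.

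The strongest peaks were found in both libraries, and the lists parted more the weaker the peaks were. Of the PBS peaks, 7385 (61.9%, interval 61.0 to 62.8) overlapped a lysine peak by at least 1 bp, and of the lysine peaks 7386 (75.3%, 74.5 to 76.2) overlapped a PBS peak. Circular shifts of the lists along the chromosomes gave 0.453% and 0.563% on average over 100 shifts. In the PBS list the share overlapped went from 28.9% in the weakest decile by −log10 q to 98.5% in the strongest, and in the lysine list from 43.1% to 99.7%. In decile 5, counted from the weakest, it was 56.2% in PBS and 72.3% in lysine. PBS peaks without a lysine partner (4541) had a median width of 381 bp against 511 bp for shared ones. The 2419 lysine peaks without a PBS partner had a median of 370 bp against 482 bp. The lists shared 3.51 Mb, which is 51.8% of the PBS length and 65.0% of the lysine length. Among peaks of 1 kb or more alone, 36.6% of PBS and 51.6% of lysine peaks overlapped one another.

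Peaks near gene ends were called in similar numbers in both libraries, and peaks deeper inside genes or between genes were fewer in lysine. Within 1 kb of either end of a protein-coding gene, 5125 PBS peaks and 4788 lysine peaks were called, and the lysine list covered 0.891 of the PBS length there. Elsewhere inside genes the numbers were 3737 and 2697 with a covered length ratio of 0.707, and between genes 3064 and 2320 with a ratio of 0.731. Peaks near gene ends made up 43.0% (42.1 to 43.9) of the PBS list and 48.8% (47.8 to 49.8) of the lysine list. Of the PBS peaks near gene ends 78.1% had a lysine partner, compared with 49.7% inside genes and 49.8% between genes. Among the 1012 genes of at least 20 kb marked in both libraries, the lysine to PBS ratio of covered length was 0.972 in the outermost 1 kb, 0.882 from 1 to 2 kb, 0.907 from 2 to 5 kb, 0.840 from 5 to 10 kb and 0.764 beyond 10 kb from the nearer end. The ratio was also lower in longer genes, from 0.877 in genes under 5 kb to 0.675 in genes of 200 kb or more. The gene table used here has no strand, so the start and the end of a gene were treated alike. With both lists held to the same number of peaks, the ratios were 0.999 near gene ends, 0.891 inside genes and 0.909 between genes.

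**Figure D1:**
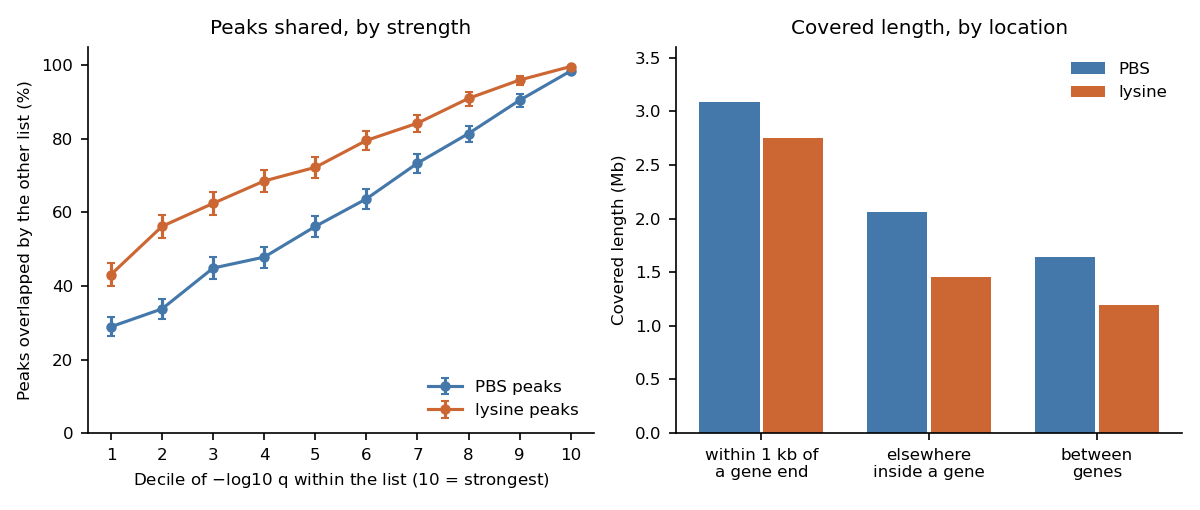
Left, percentage of peaks overlapped by a peak of the other list (y axis) in each decile of the list ranked by −log10 q (x axis), with 95% Clopper-Pearson intervals as bars, for the PBS and lysine lists. Right, covered length in Mb by location for each library. The overlap reaches 98.5% and 99.7% in the strongest decile, and the bars are closest within 1 kb of a gene end (ratio 0.891).

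Over 21900 protein-coding genes, 2488 had at least 500 bp covered in PBS and 1976 in lysine, and such genes are called marked here. Both libraries marked 1365 genes, PBS alone 1123 and lysine alone 611, and at a −log10 q of at least 5 these numbers were 476, 582 and 276. Most genes marked in one library alone still had some covered length in the other: 788 of the 1123 and 476 of the 611. Any peak at all was found on 7446 genes (34.0%) in PBS and 6870 (31.4%) in lysine. Among the 3099 genes marked in either library the median difference, lysine minus PBS, was -150 bp (quartiles -580 and 180). It was -45 bp with equal numbers of peaks and -295 bp with peaks of 1 kb or more alone. Covered length was shorter in lysine in 1915 of them and longer in 1180. A loss of at least 2 kb was found in 49 genes and a gain of that size in 1, Fgd3 (404 bp in PBS and 2448 bp in lysine), named here after its values were seen. The counts of losses and gains moved with the treatment of the peaks, from 6 to 110 losses and from 0 to 24 gains. Of the 103 genes chosen by rule, 20 kept their direction under all alternatives run on them, and 52 showed no difference at a −log10 q of at least 5. Genes on which neither library kept a peak are counted as showing no difference.

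Among genes marked in both libraries, Il3ra and Runx1 had the largest shortfall in lysine. Il3ra (chromosome 14, 14345912 to 14355493) had 7228 bp covered in PBS and 2718 bp in lysine. Its 2 PBS peaks of 4457 and 3085 bp stood opposite 3 lysine peaks of 886, 683 and 1408 bp at the same place. Runx1, a haematopoietic transcription factor (chromosome 16, 92601466 to 92826074), had 5111 and 1278 bp, in 8 PBS and 3 lysine peaks. Next were the bromodomain gene Baz2b (4491 and 881 bp), the splicing regulator Mbnl1 (4720 and 1431 bp), the sialyltransferase St3gal1 (4123 and 1018 bp) and Marchf1 (3566 and 689 bp). Marchf1 (chromosome 8, 65618009 to 66472841) encodes a ubiquitin ligase that limits surface MHC class II and Cd86. Vps13d (4471 and 1616 bp), the receptor phosphatase Ptprj (5736 and 2957 bp), the adhesion scaffold Nedd9 (5172 and 2418 bp) and the inositol trisphosphate receptor Itpr1 (4357 and 1726 bp) completed the 10. Baz2b, Vps13d and Ptprj overlap Gm13570, Dhrs3 and Gm46752. With peaks of −log10 q of at least 5 alone, Baz2b, St3gal1 and Marchf1 were longer in lysine by 484, 831 and 236 bp, and Mbnl1 showed no difference. By narrow blocks the shortfall of Il3ra was -1088 bp, smaller than those of Runx1 (-2762 bp), Baz2b (-2228 bp), Nedd9 (-2107 bp) and other genes of the 10.

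Covered in PBS and without any lysine peak were H2-Ab1 (2442 bp), the beta chain of an MHC class II molecule (chromosome 17, 34263227 to 34269418), and Jmjd1c (2076 bp), which encodes a Jumonji domain protein and overlaps Reep3. Sephs1 (1929 bp), the receptor Gpr55 (1895 bp), the phosphoinositide 3-kinase subunit Pik3r5 (1890 bp) and the potassium channel Kcnn3 (1821 bp) followed. Also in this group were the endosomal SNARE Stx7 (1751 bp), the splicing regulator Esrp1 (1743 bp) and Pid1 (1742 bp). A gene without a called peak can still carry the mark below the threshold. The H2-Ab1 region was a single wide peak of modest strength in its list, with a fold of 3.82 and a −log10 q of 2.42, and at a fold of at least 4 neither library had a peak on the gene. By narrow blocks its difference was -343 bp. Gpr55 had no peak in either library at a −log10 q of at least 2. Of the genes named here, only Jmjd1c (-509 bp) and Kcnn3 (-962 bp) kept a PBS peak at a −log10 q of at least 5.

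**Figure D2:**
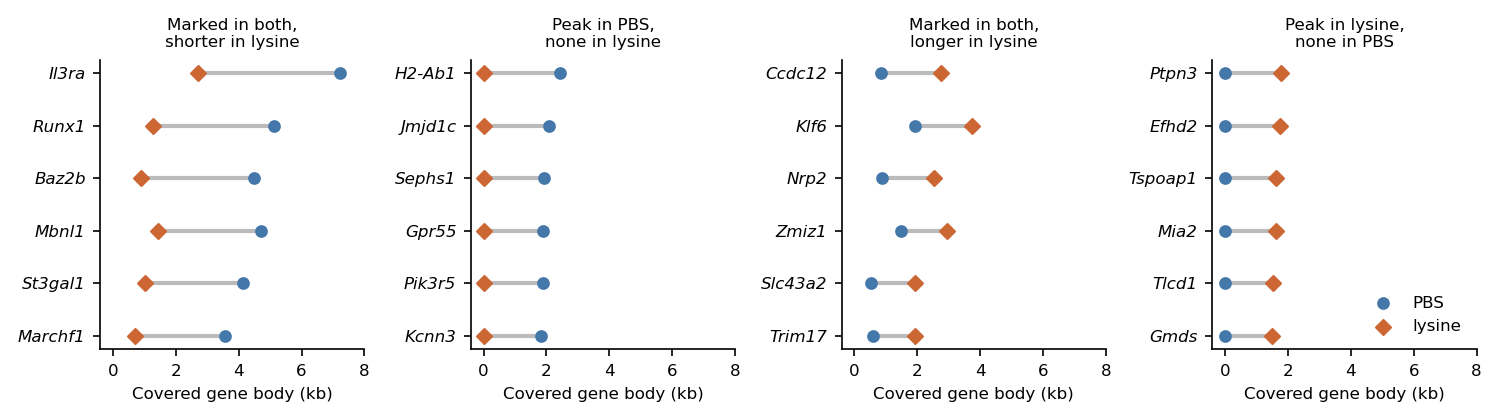
Covered gene body in kb (x axis) for the first 6 genes of each of 4 rules by size of the difference, PBS as circles and lysine as diamonds, 1 library each. Il3ra spans the widest gap, from 7228 to 2718 bp, and among genes with a peak in 1 library alone H2-Ab1 is the longest with 2442 bp.

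Fewer genes went the other way, and by shorter lengths. Of genes marked in both, the longest gains in lysine were at Ccdc12 (843 bp in PBS and 2769 bp in lysine), Klf6 (1925 and 3738 bp), Nrp2 (881 and 2543 bp), a receptor for semaphorins, and the transcriptional coactivator Zmiz1 (1494 and 2941 bp). Slc43a2, a transporter of neutral amino acids (chromosome 11, 75529915 to 75577575), had 521 and 1935 bp. The remaining 5 were Trim17 (585 and 1937 bp), the Src-like adaptor Sla (522 and 1841 bp), Fnbp1 (1780 and 3019 bp), the MHC class II invariant chain Cd74 (900 and 2134 bp; chromosome 18, 60803849 to 60812652) and the clock gene Per1 (2284 and 3470 bp). Zmiz1, Trim17 and Sla overlap Gm45915, H2aw with H3f4, and Tg. Of these 10 gains 7 turned under some alternative, against 3 of the 10 losses. Nrp2 and Zmiz1 were shorter in lysine at a −log10 q of at least 2 (-881 and -743 bp) and at a fold of at least 4 (-324 and -165 bp), and Klf6 was shorter by its narrow blocks (-258 bp). Trim17 turned at a −log10 q of at least 2 (-162 bp), and Sla, Fnbp1 and Per1 at a −log10 q of at least 5 (-522, -1066 and -1977 bp). Cd74 had no peak with a −log10 q of at least 2 in either library, and Ccdc12 and Slc43a2 did not turn under any alternative, though Slc43a2 showed no difference at a −log10 q of at least 5.

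Covered in lysine and without any PBS peak were the phosphatase Ptpn3 (1784 bp), the calcium-binding Efhd2 (1752 bp), Tspoap1 (1627 bp), Mia2 (1621 bp) and Tlcd1 (1532 bp, overlapping Rpl23a). Gmds (1482 bp), Sctr (1477 bp, overlapping Cfap221), Ankrd13a (1433 bp), Serpinb1b (1410 bp) and Hfe (1402 bp), a regulator of iron uptake, followed. At a −log10 q of at least 5, 9 of these 10 genes had no peak in either library, and Hfe had 376 bp in lysine. Already at a −log10 q of at least 2 Serpinb1b had no peak, and Gmds and Hfe had 455 and 376 bp. Dot1l itself (chromosome 10, 80755101 to 80795461) was marked in both libraries, with 537 bp in PBS and 634 bp in lysine, and at a fold of at least 4 the difference turned to -234 bp.

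**Figure D3:**
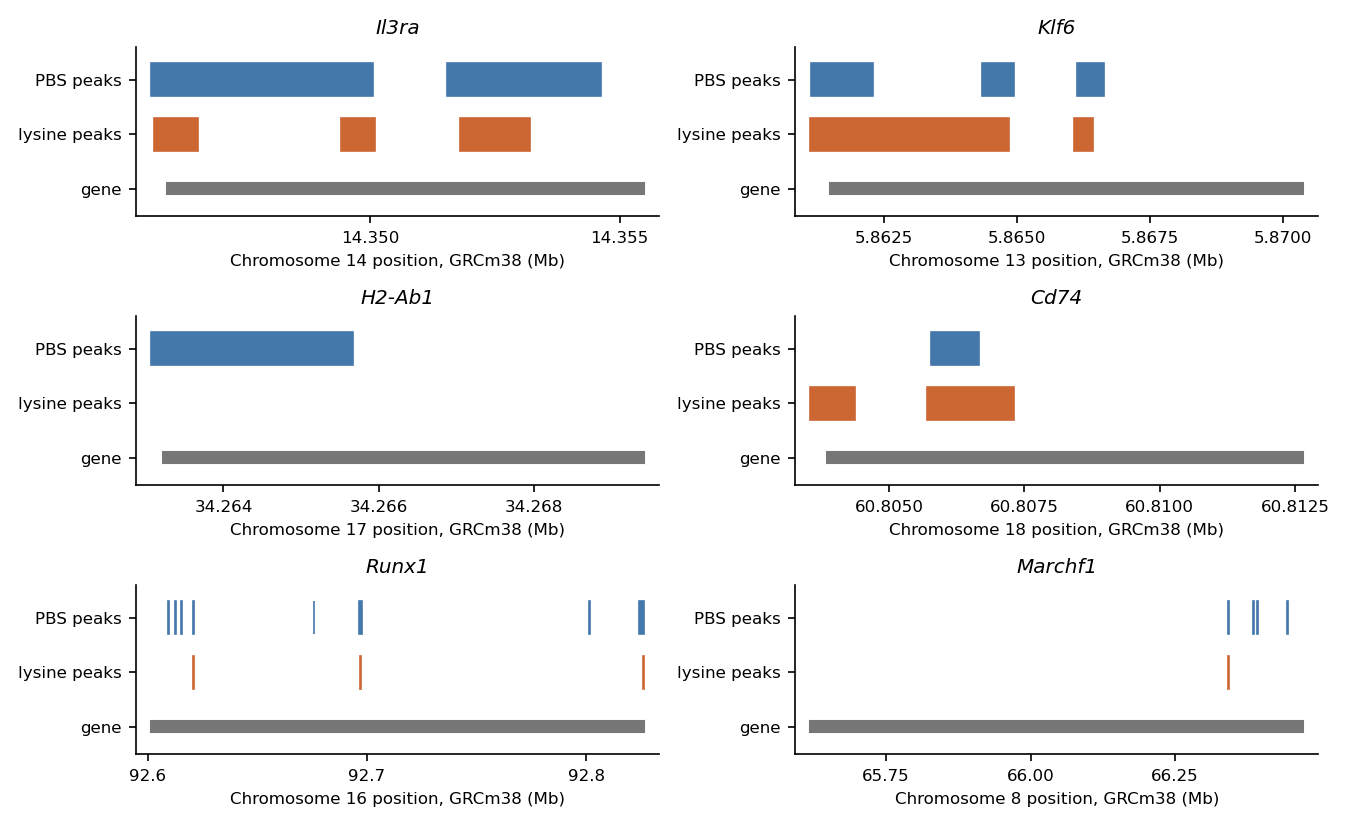
Called H3K79me2 peaks of the PBS and lysine libraries and the gene body at 6 loci, drawn to scale along chromosome position in Mb on GRCm38. Il3ra, Runx1, Marchf1 and H2-Ab1 have more covered length in PBS, and Klf6 and Cd74 have more in lysine (2134 against 900 bp at Cd74). Marchf1 turned at a −log10 q of at least 5 and Klf6 by its narrow blocks.

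Lists of antigen presentation and dendritic cell identity genes had less covered length in lysine as totals, within the range of random lists. Of 17 MHC class II presentation genes, 10 had a peak in PBS and 7 in lysine and 5 and 4 were marked, with 11.1 kb covered in PBS and 6.34 kb in lysine. The largest shortfalls were those of H2-Ab1 and Marchf1, while H2-DMa, which overlaps Brd2, had 2603 and 2345 bp, and Cd74 was longer in lysine. Of 17 MHC class I presentation genes, 14 and 12 had a peak and 2 and 2 were marked (4.738 and 3.499 kb). Tapbp, the peptide-loading factor tapasin, had 1361 and 0 bp, and Tap2 668 and 611 bp. The immunoproteasome subunit Psmb10 had 0 and 1019 bp, and no peak in either library at a −log10 q of at least 2. Among 32 genes of dendritic cell identity and maturation 18 had a peak in PBS and 17 in lysine, and 11 and 6 were marked (15.9 and 10.8 kb). The costimulatory ligand Cd86 had 2478 and 1081 bp, the inhibitory receptor Sirpa 1385 and 359 bp, and Cd274, which overlaps Plgrkt, 1506 and 1591 bp, turning to -1191 bp at a −log10 q of at least 2. Covered length was shorter in lysine in 7, 10 and 11 members of these 3 lists and longer in 3, 5 and 8, and the median difference was 0, -28 and 0 bp. The lysine totals were 0.571, 0.738 and 0.679 of the PBS totals, compared with 0.796 over all peaks. The mean differences lay at percentiles 8.11, 42.0 and 24.0 among 10000 random lists matched on covered length. Under the alternatives the differences in total ranged from -5.992 to -0.152 kb, from -2.258 to -0.185 kb and from -6.372 to -1.366 kb. Those nearest to 0 came at a −log10 q of at least 5 for both MHC lists and by narrow blocks for the dendritic cell list.

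Cytokine, Toll-like receptor and interferon genes had less covered length in lysine as lists, within the range of random lists. The Toll-like receptor list had the smallest shortfall, with 0.889 of its PBS length in lysine against 0.796 over all peaks. Of 29 cytokine and chemokine genes 10 had a peak in each library, and 7.04 kb were covered in PBS and 3.86 kb in lysine (percentile 11.7). Il15 had 2674 and 374 bp and the interleukin-1 antagonist Il1rn 1007 and 553 bp. Il1a had 0 and 1043 bp, and no peak in either library at a −log10 q of at least 2. Of 35 genes of Toll-like receptor and NF-kB signalling 22 had a peak in each library, with 18.7 and 16.6 kb covered (percentile 76.4). Irak2 had 4285 and 3317 bp, Rel 1701 and 597 bp, Tlr13 1413 and 308 bp, and Nfkbib 1428 and 1244 bp. This list's total turned to 1.441 kb more in lysine with peaks of 1 kb or more alone, and differed by -0.073 kb with equal numbers of peaks. It also turned to 0.504 kb more in lysine at a fold of at least 4, where Irak2 turned as well (248 bp). Tlr13 and Nfkbib turned by their narrow blocks (308 and 34 bp). In the type I interferon response 17 of 37 genes had a peak in PBS and 14 in lysine (7.63 and 4.08 kb, percentile 8.81). Adar, an RNA editing enzyme that overlaps Chrnb2 here, had 885 and 0 bp, and Trim25 807 and 0 bp. Tyk2 had 1405 and 655 bp and Ifnar2 703 and 359 bp, and these 2 turned at a −log10 q of at least 2 (305 and 59 bp). The cytokine total differed by -6.1 to -1.391 kb under the alternatives, the smallest with peaks of 1 kb or more alone. The interferon total, at -3.55 kb, was -0.401 kb at a fold of at least 4, -0.798 kb at a −log10 q of at least 5 and -1.152 kb with equal numbers of peaks.

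Genes that handle the added amino acid differed in both directions, within the range of random lists. Of 28 genes of lysine transport and catabolism, 11 had a peak in PBS and 13 in lysine, with 5.74 and 6.87 kb covered (percentile 94.1). In lysine 6 of them were shorter and 7 longer, 5 were marked in each library, and the median difference was 0. The cationic amino acid transporter Slc7a1 had 746 and 1019 bp, and Slc3a2, the shared heavy chain of several amino acid transporters, 1742 and 578 bp. Slc7a6 had 0 and 1198 bp and Slc36a4, named here after its values were seen, 0 and 1157 bp. Each of these gains is more than the excess of the whole list (1.128 kb). Slc7a6 showed no difference at a −log10 q of at least 5. The list's total turned to -0.21 kb at a −log10 q of at least 5 and to -0.955 kb with peaks of 1 kb or more alone. In amino acid sensing and mTORC1, 27 of 38 genes had a PBS peak and 23 a lysine peak (15.3 and 10.1 kb, percentile 18.6). Castor2, of an arginine sensor family, had 1448 and 0 bp, and no peak in either library at a −log10 q of at least 2. The folliculin partners Fnip2, overlapping Gm17359, and Fnip1 had 2210 and 909 bp and 1196 and 859 bp. At a −log10 q of at least 5 this list's total turned to 1.44 kb, with Fnip2 at 254 bp and Fnip1 at 651 bp. The integrated stress and unfolded protein response list had 25 of 30 genes with a peak in each library (18.1 and 12.7 kb, percentile 31.1). Slc7a11, the cystine transporter, had 2675 and 1896 bp, Slc7a5 1772 and 1766 bp, and Cebpb 1357 and 0 bp. The difference in this list's total ranged from -6.609 to -1.826 kb under the alternatives.

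Among genes of H3K79 methylation and its partners, 24 of 31 had a peak in PBS and 23 in lysine (12.7 and 10.5 kb, percentile 45.2). The elongation factors Aff1 and Ell had 4303 and 3047 bp and 1099 and 103 bp, and Aff4 had 563 and 826 bp. The list's total turned to 0.508 kb with peaks of 1 kb or more alone, as did Ell (6 bp), and Aff4 turned at a −log10 q of at least 5 (-563 bp). Of 24 genes of methionine and S-adenosylmethionine metabolism, which supplies the methyl donor, 16 and 15 had a peak (8.24 and 6.08 kb, percentile 44.7). Mat2a, the synthetase of that donor, which overlaps Ggcx, had 572 and 1409 bp, Ahcyl1 157 and 1083 bp, Amd1 1291 and 59 bp, and Mthfd1 1372 and 532 bp. The total of this list differed by -3.879 to -0.289 kb under the alternatives. Mat2a turned to -572 bp at a −log10 q of at least 2, and Mthfd1 to 9 bp at a −log10 q of at least 5. Glycolysis was the most densely marked function list, with 13 of 24 genes marked in PBS and 12 in lysine and a peak on 17 and 15 (14.8 and 15.5 kb, percentile 95.2). The phosphofructokinase Pfkp, overlapping Pitrm1, had 1185 and 2313 bp, Gapdh 1336 and 1739 bp, and Hk3, overlapping Unc5a, 1244 and 0 bp. The list's total turned to -1.012 kb at a −log10 q of at least 2 and -0.473 kb over genes that overlap no other, Gapdh to -1336 bp at a −log10 q of at least 5, and Pfkp to -290 bp at a fold of at least 4.

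Of 50 ribosomal protein genes 43 had a peak in PBS, the highest share of the function lists there, and 39 in lysine. Mostly short stretches were covered, with 2 and 3 genes marked and totals of 9.50 and 9.46 kb. Their median difference was 8 bp (percentile 96.0) and their mean -0.9 bp (percentile 82.6), so the signs differ. The difference in total ranged from -1.366 to 0.555 kb under the alternatives. Rpl18, overlapping Sphk2, had 637 and 453 bp, Rpl24, overlapping Zbtb11, 134 and 897 bp, and Rps23 1022 and 0 bp. In lysosome and autophagy 26 of 36 genes had a PBS peak and 27 a lysine peak (18.6 and 12.7 kb, percentile 20.9). The cholesterol carrier Npc2 had 2981 and 1570 bp, the protease Ctsb, overlapping Fdft1, 2096 and 1745 bp, and Atg7 2314 and 421 bp, and Npc2 and Ctsb turned by their narrow blocks (293 and 381 bp). The lysosome total differed by -8.341 to -0.984 kb under the alternatives. Of 35 cell death and ferroptosis genes, 27 had a peak in PBS and 25 in lysine, and 14 and 10 were marked (27.5 and 22.5 kb, percentile 38.2; differences of -6.968 to -0.982 kb under the alternatives). The caspase-8 regulator Cflar had 5107 and 5159 bp, the BH3-only gene Bbc3 3356 and 3942 bp, the inflammasome sensor Nlrp3 2089 and 346 bp, and Nfe2l2 3102 and 1556 bp. Cflar turned to -2500 bp at a −log10 q of at least 2, Bbc3 to -212 bp by narrow blocks, and Nlrp3 to 346 bp at a −log10 q of at least 5. Across the 15 function lists, 12 had more members marked in PBS, 1 more in lysine and 2 the same number. The median difference was 0 in 10 of them.

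**Figure D4:**
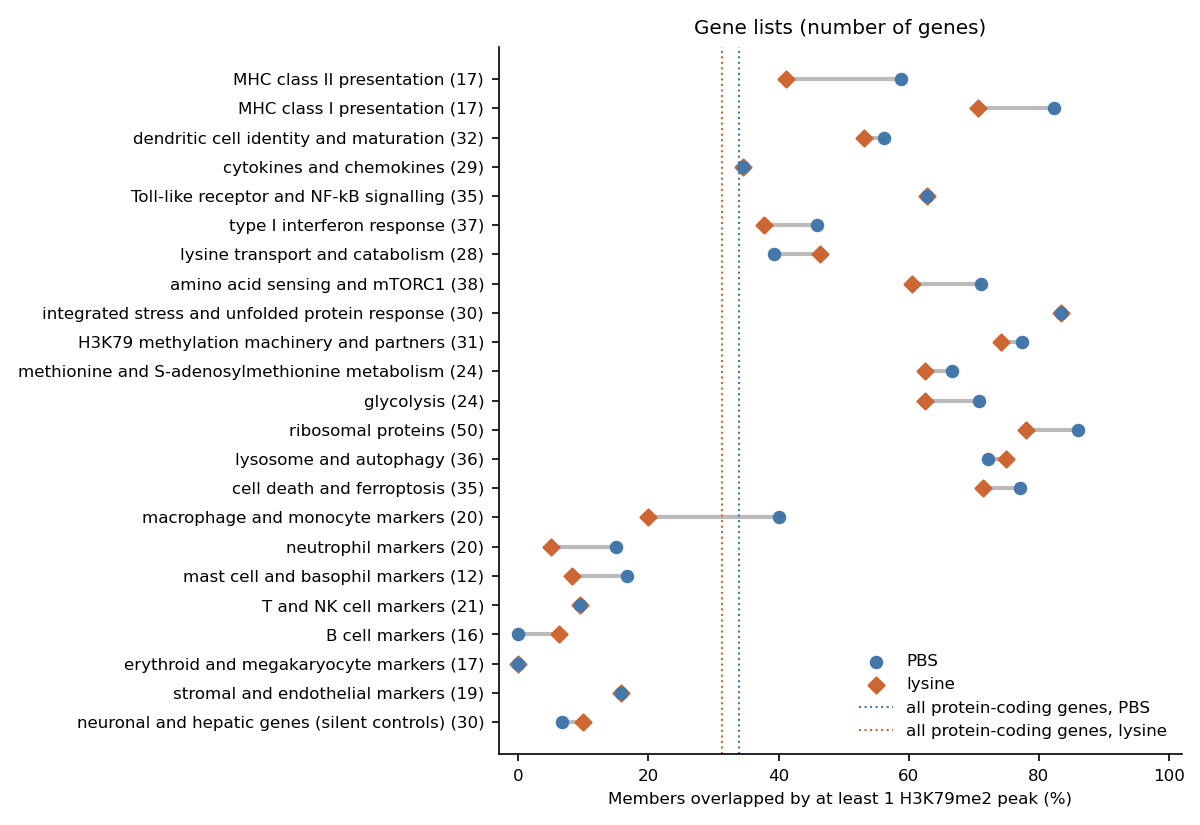
Percentage of each list's genes overlapped by at least 1 peak (x axis), PBS as circles and lysine as diamonds, with the number of genes in brackets and dotted lines at the values of all protein-coding genes (34.0% and 31.4%). Ribosomal protein genes reach 86.0% in PBS and 78.0% in lysine, and B cell, T cell and erythroid markers stay at or under 9.52%.

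Markers of other bone marrow cells were covered rarely in both libraries, apart from those of macrophages and monocytes in PBS, some of which dendritic cells also express. A missing peak does not show that a cell type was absent. Of the 32 genes of dendritic cell identity and maturation, 13 had no peak in either library. Spi1 and Csf2rb, named here after their values were seen, were among them. Of 20 macrophage and monocyte markers 8 had a peak in PBS and 4 in lysine. Csf1r was the only one marked, with 1171 and 1160 bp, turning to 819 bp more in lysine at equal numbers of peaks, and Cx3cr1 had 488 and 340 bp, Mertk 341 and 0 bp and Cd14 340 and 0 bp. A peak was found on 3 and 1 of 20 neutrophil markers (Ltf 499 and 346 bp, Mmp8 444 and 0 bp) and on 2 and 1 of 12 mast cell and basophil markers (Hdc 453 and 384 bp, turning to 384 bp more in lysine at equal numbers of peaks, and Il1rl1 380 and 0 bp). T and NK cell markers had 2 of 21 in each library (Cd3d 519 and 555 bp, Klrb1c 487 and 398 bp, turning to 398 bp more in lysine at a −log10 q of at least 5), B cell markers 0 and 1 of 16 (Rag2, overlapping Iftap, 290 bp in lysine and none at a −log10 q of at least 2), and the 17 erythroid and megakaryocyte markers none. Of 19 stromal and endothelial markers 3 had a peak in each library, with Runx2, overlapping Supt3, at 2973 and 1734 bp and Vwf at 970 and 309 bp, turning to 29 bp more in lysine by narrow blocks. Neuronal and hepatic genes, listed with some of muscle and pancreas and taken as silent in these cells, had 2 of 30 with a peak in PBS and 3 in lysine. Among them were Syp (427 and 477 bp) and Apoa2 (456 and 351 bp, overlapping Tomm40l). The share of these genes with a peak lay at percentile 0.000 in PBS and 0.110 in lysine among random lists matched on gene length.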

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

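Peaks on unplaced sequences and on the mitochondrial genome were counted apart because no result above describes them. They are included in the peak numbers, covered lengths, shares of overlapped peaks and location counts of the report. Each count but the lysine mitochondrial one stood above the limit of 3 that a count of 0 allows. Unplaced sequences held 8 peaks in the PBS list and 8 in the lysine list. The mitochondrial genome held 4 peaks in the PBS list and 3 in the lysine list, with folds from 1.46 to 2.26, near the low end of both lists. No explanation was tested for these.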

How the results depend on the processing

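The lists had fewer lysine than PBS peaks under every alternative treatment of the peaks except equal numbers, which sets the ratio to 1, with ratios from 0.708 to 0.827. Of 904 values of 103 named genes under the alternatives, 727 kept their direction, 126 showed no difference and 51 reversed, and 69 genes did not reverse under any. Part of this agreement holds by construction. Autosomes alone changed only named genes on the X, and genes that overlap no other gene kept their main values. Fewer were stable: 39 genes showed some difference under all alternatives run on them, and 20 kept their direction under all. No difference was left in 52 genes at a −log10 q of at least 5, in 34 with peaks of at least 1 kb alone, in 23 at a fold of at least 4 and in 7 at a −log10 q of at least 2. These counts include genes on which neither library kept a peak, so they do not mean equal coverage. Of 135 list totals 13 reversed, and 9 of the 15 function lists did not reverse. Reversed genes and lists are given as lysine minus PBS; the cause was not tested, apart from fewer or shorter peaks entering by construction. No paired analysis was possible because each condition has 1 library and the labels give no replicate numbers, and for the same reason no replicate could be left out. The first 5 kb of genes as the gene region was not run, since it needs the strand. Depth limits which weak or wide regions are called, and it is unknown here. Chosen after seeing the data were the location ratios under peak alternatives, the 10 kb zone, partners within 1 kb, mean differences and totals over lists, and totals over families.

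At a −log10 q of at least 2, 76.6% of lysine peaks were shared, 2 genes gained at least 2 kb, and 2 lists had more members marked in lysine. Reversed were Nrp2 (-881 bp), Zmiz1 (-743), Trim17 (-162), Cd274 (-1191), Cflar (-2500), Mat2a (-572), Tyk2 (305), Ifnar2 (59), glycolysis (-1.012 kb) and ribosomal proteins (0.04 kb).

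At a −log10 q of at least 5, PBS had 4423 peaks over 2772 kb and lysine 3384 over 2088 kb, with 56.0% and 73.2% shared. Genes marked in both, PBS alone and lysine alone were 476, 582 and 276, with 13 losses and 4 gains of at least 2 kb, and 2 lists had more members marked in lysine. Location ratios were 0.838 near gene ends, 0.603 inside and 0.690 between genes. Reversed were Baz2b (484 bp), St3gal1 (831), Marchf1 (236), Zmiz1 (-355), Sla (-522), Fnbp1 (-1066), Per1 (-1977), Fnip2 (254), Fnip1 (651), Aff4 (-563), Mthfd1 (9), Gapdh (-1336), Cflar (-1189), Nlrp3 (346), Klrb1c (398), lysine transport and catabolism (-0.21 kb), mTORC1 (1.44 kb) and glycolysis (-1.446 kb).

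At a fold of at least 4, 60.2% of PBS peaks were shared, 24 genes lost and 4 gained at least 2 kb, and the ratio inside genes was 0.672. Reversed were Nrp2 (-324 bp), Zmiz1 (-165), Dot1l (-234), Cd274 (-58), Ifnar2 (59), Irak2 (248), Pfkp (-290) and Toll-like receptor signalling (0.504 kb).

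With equal numbers of peaks, 68.7% of PBS and 68.7% of lysine peaks were shared and the median difference of marked genes was -45 bp. There were 20 losses and 6 gains of at least 2 kb, 3 lists had more members marked in lysine, and the location ratios were 0.999, 0.891 and 0.909. Reversed were Csf1r (819 bp), Hdc (384), Ifnar2 (59), Tyk2 (305) and ribosomal proteins (0.555 kb).

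With peaks of at least 1 kb alone, 1180 PBS peaks covered 1739 kb and 835 lysine peaks 1222 kb, with 36.6% and 51.6% shared. Genes marked in both, PBS alone and lysine alone were 289, 508 and 284, the median difference was -295 bp, 31 genes lost and 8 gained at least 2 kb, and 2 lists had more members marked in lysine. The location ratios were 0.741, 0.666 and 0.674. Reversed were Cd274 (-1150 bp), Csf1r (1160), Ell (6), Irak2 (213), H3K79 methylation (0.508 kb), Toll-like receptor signalling (1.441 kb) and lysine transport and catabolism (-0.955 kb).

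Joining peaks within 2 kb gave 110 losses and 24 gains of at least 2 kb and reversed Irak2 (756 bp). By narrow blocks 60.5% and 73.6% were shared, 6 genes lost and 0 gained at least 2 kb, and 2 lists had more members marked in lysine. Reversed by narrow blocks were Klf6 (-258 bp), Nrp2 (-456), Zmiz1 (-573), Bbc3 (-212), Ctsb (381), Gapdh (-951), Mat2a (-572), Nfkbib (34), Npc2 (293), Tlr13 (308), Tyk2 (305), Vwf (29), glycolysis (-0.246 kb) and ribosomal proteins (0.534 kb). Over genes that overlap no other gene, glycolysis reversed (-0.473 kb).

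With at least 1 bp as the minimum, 5844 genes were marked in both and 1026 in lysine alone, and 2 lists had more members marked in lysine. With at least 2000 bp, 76 were marked in both, 149 in PBS alone and 30 in lysine alone, and 7 lists had more members marked in PBS. Requiring overlap of 0.5 of the peak gave 56.0% and 70.2% shared, and of 0.5 of both peaks 52.6% and 63.9%. A 10 kb zone gave ratios of 0.844 near gene ends and 0.660 inside genes, and the number of peaks, placed by midpoint, in place of covered length gave 0.934 near gene ends.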

Other observations

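The gene families and their random lists, the long non-coding genes, and the tests of depth and of the calling threshold were chosen after the main results were seen. Families used in sensory or epithelial tissue or in body patterning had hardly any peak. Of 1110 olfactory receptor genes 0 had a peak in PBS and 3 in lysine, of 353 vomeronasal receptor genes 1 and 2, of 70 defensin genes 0 and 1, and of 39 genes of the homeobox clusters 1 and 1. Housekeeping families were covered far more often: 30 and 24 of 40 proteasome subunit genes, 45 and 44 of 78 mitochondrial ribosomal protein genes, and 22 and 21 of 40 complex I genes. The lysine to PBS ratio of covered length was 0.985 for RNA helicase genes, 0.977 for complex I, 0.907 for mitochondrial ribosomal proteins, 0.870 for Zfp zinc finger genes, 0.850 for Slc transporters and 0.789 for the proteasome. It was lowest for translation initiation factor genes (0.621, with 16.0 and 9.94 kb) and RAB GTPase genes, which direct membrane traffic (0.615, with 23.5 and 14.4 kb). The mean differences of these 8 families lay at percentiles 8.31 to 86.5 among matched random lists, so none stood outside the 5 to 95 range. Kruppel-like factor genes were looked at because of Klf6, so their direction is not independent of it. Of 17 members 4 were marked in PBS and 7 in lysine, with 6.85 and 10.2 kb covered, an excess of 3.397 kb (percentile 99.8). It shrank to 1.584 kb without Klf6, to 1.796 kb over genes that overlap no other gene and to 0.005 kb by narrow blocks.

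Among 7323 long non-coding genes over 1 kb from any protein-coding gene, 446 had a peak in PBS and 374 in lysine, with 263 and 200.5 kb covered, a ratio of 0.763. Malat1 (chromosome 19, 5795690 to 5802672) had the largest difference, with 4860 bp in PBS and 296 bp in lysine. Lncpint (chromosome 6, 31093563 to 31218474) had 4390 and 2860 bp.

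The first pattern is that the lysine library had fewer peaks, of nearly the same median width. A lower depth as seen by the peak caller would give lysine peaks less significance at the same fold, by a factor of 0.770 to explain the peak number. The ratio of −log10 p at matched folds was 1.003 (bootstrap interval 1.001 to 1.004), which argues against it, although the read totals themselves are unknown. A stricter calling threshold for lysine would let the peak number ratio rise at a higher common threshold. At a −log10 q of at least 5 in both lists the ratio was 0.765 (0.731 to 0.8003), against 0.822 over all peaks. The −log10 q is adjusted within each list, so an equal value can be a stricter −log10 p in 1 list and lower the ratio. At a fold of at least 4, which has no such adjustment, it was 0.803. These values argue against a stricter threshold as the whole cause. A weaker immunoprecipitation of the lysine library cannot be told apart from an effect of lysine on the mark, because there is 1 library per condition, and both stay open.

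The second pattern is the larger difference inside and between genes than near gene ends. If it came only from weaker peaks away from gene ends, peaks of equal strength would be shared about equally often, but within deciles of −log10 q PBS peaks near gene ends were shared more often by 18.8 percentage points (bootstrap interval 17.4 to 20.3, and from 2.74 to 26.8 by decile), against 28.3 points without this grouping. For lysine peaks the difference was smaller, 9.42 points (bootstrap interval 7.66 to 11.1, and from 0.209 to 16.4 by decile) against 16.8. The grouping thus reduced the difference in both lists without removing it. A peak's own −log10 q is a noisy measure of its strength, so deciles of it cannot make strength equal. Strength as the whole cause therefore stays undecided. Whether the larger difference away from gene ends follows from the lower number of lysine peaks alone stays undecided as well. With equal numbers, the ratio elsewhere divided by that near gene ends was 0.890. Its bootstrap interval of 0.849 to 0.941 crosses the bound of 0.9 set for this question. A weaker immunoprecipitation of the lysine library, which may affect broad low regions first, and an effect of lysine cannot be told apart with 1 library per condition.

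The third pattern is the lower total covered length of MHC class II genes in lysine, for which H2-Ab1 and Marchf1 alone more than account. The overall loss of covered length is a candidate explanation, and the list's mean difference at percentile 8.11 of matched random lists lies inside the 5 to 95 range that it needs. The list's median difference, the measure first planned, was 0 and lay at percentile 52.0. A loss specific to these genes as a hypothesis is therefore not needed by these data, and it is not excluded, with 17 genes and 1 library per condition.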
